A study of Mus musculus with 14 samples.

How the data were processed

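Gene expression values of 14 mouse lung libraries were analysed. Alveolar type 1 (AT1) cells, the thin gas-exchange cells of the alveolus, had been purified by flow sorting at postnatal day 5 (P5) and gave 3 control and 3 mutant libraries. Alveolar type 2 (AT2) cells, the surfactant-secreting cells, gave 3 control and 3 mutant libraries, taken at P8, P8 and P9 in each arm. Whole lung at P14 gave 1 control and 1 mutant library. Groups were taken from the sample labels, which name the crosses by Nkx2-1 with Aqp5 (AT1 cells and lung) or with Sftpc (AT2 cells). The allele and the deleted part of the gene are not given in the sources used here, and neither is the way the AT2 cells were isolated.

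Per the labels' protocols, libraries were made from poly(A)-selected RNA and sequenced as paired-end reads of 76 nucleotides. Per the submitters' processing notes, TopHat2 2.0.14, Bowtie2 2.2.3 and Cufflinks 2.2.1 were used with the mm10 build, together with Cuffdiff for the AT1 and lung libraries and Cuffnorm for the AT2 libraries. The gene annotation and the use of strand are not given in the sources used here. Overlapping genes, antisense genes and near-identical copies are therefore uncertain, and small nucleolar RNA and microRNA loci, many of them inside host genes, were erratic between replicates. The expression values deposited by the authors are FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library), one column per library. The log2 fold changes and the test p-values in the authors' deposited table were used only to describe that table. AT1 and AT2 values came from separate tables, with 23793 loci for AT1 cells and lung and 32609 loci for AT2 cells, and were normalized separately. Levels set side by side across cell types are therefore descriptive, and tests were made within a table or on the difference of 2 within-table contrasts. Spreadsheet conversion had turned 26 gene names in the first table and 23 in the second into dates, and those loci could not be named.

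FPKM values hold no read counts, so depth in reads is unknown and neither a counting interval nor a detection floor was given. Steps between low FPKM values gave relative depths of 1 to 1.64 among AT1 libraries and 0.865 to 1.54 among AT2 libraries, each against control A. These are weak estimates, since 12.4 to 17.6% of the low loci sat at the commonest ratio. Summed FPKM differed between libraries. In the AT2 table, mitochondrially encoded transcripts took 33.7, 27.7 and 14.0% of the total in controls A to C and 12.8, 11.5 and 8.85% in mutants A to C. The AT1 and lung table listed no such loci, and small RNA loci took up to 32.9% of a library there (P14 control lung).

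Values were transformed as log2(FPKM + 1), and a gene was kept where at least 3 of the libraries compared reached 1 FPKM. Fold changes on this scale understate the change of genes with low values. Genes were tested with limma 3.58.1 (moderated statistics with a mean-dependent prior variance) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Every adjusted p for a gene comes from limma. AT1 and AT2 libraries were fitted separately. Another fit, over the 12 cell-type libraries, tested the AT2 effect minus the AT1 effect (an interaction term). Overlap of calls was tested with a two-sided Fisher's exact test. Gene lists for cell types, pathways and stress responses were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists, and lists with fewer than 3 measured members were not tested. The same lists were tested with camera at an estimated correlation and with fry, which asks whether a list's genes move one way on balance. Some lists share members, so their results are not independent. Krt8, Krt19 and Cldn4 are in the pan-epithelial and transitional lists, and Abca3, Lpcat1 and Scd1 in the AT2 cell and surfactant lipid lists. Whole lung, with 1 library per group, was given no test; each list's median log2 ratio was placed among those of 10000 random lists of the same size matched on mean expression, over genes at 5 FPKM or more in the higher library. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9 handled tables and plots. The lists, the tests, the thresholds and the rule for naming genes were fixed before the data were examined, as were the alternatives except those said to be chosen after seeing the data.

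The rule named Nkx2-1, the 10 genes with the largest increase and the 10 with the largest decrease per cell type among called genes at 5 FPKM or more in the higher group with no overlap between arms, and up to 4 called members per list. For the interaction it named 5 genes in each direction, and for the lung the 10 largest ratios in each direction and up to 2 members per list. The text uses a shorter choice, and genes named for one comparison are also given in others. Gene coordinates are from a GENCODE annotation of GRCm38, the assembly called mm10. The steps were tested on simulated data built from the same libraries with 100 genes altered 2-fold and 100 altered 4-fold per comparison. In AT1 cells (12612 genes) 58% of 2-fold and 96% of 4-fold changes were called, with 3.75% of calls false. In AT2 cells (11610 genes) these shares were 83%, 97% and 3.74%. For the interaction (10336 genes) they were 51%, 95% and 8.18%. All genes other than the altered ones were simulated without a change, whereas far more genes were called in the real comparisons. The altered genes were drawn only from those with a mean log2(FPKM + 1) above that of 5 FPKM. These shares are therefore not rates for genes with lower values. Recovery was not split further by expression level. They describe the simulation and need not hold for the real libraries.

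The labels letter the libraries A to C in both arms without saying what a letter means, so the fits had no block. Deviations of same-lettered AT1 libraries from their group means correlated across genes at 0.24, 0.36 and 0.48, against -0.24 to -0.10 for other pairs, so letters were taken to pair the AT1 libraries, from the data and not from the labels. AT2 letters gave 0.11, -0.12 and 0.13 and were not taken to pair them. Nearly all p-values deposited by the authors equal those of a test paired by letter, in both cell types. The labels do not say that replicates are separate animals, so p-values measure the spread between these libraries. No library duplicated another, and rank correlations within groups ran from 0.934 to 0.985. Alternatives included another pseudocount, other filters, 3 rescalings planned and 1 chosen after seeing the data, other variance models, list tests with no filter (also chosen after seeing the data), the replicate block, postnatal day as a term, and leaving out each library.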

Results

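Gene expression was measured by RNA-seq in mouse lung carrying a mutation of Nkx2-1, which encodes a homeobox transcription factor of lung and thyroid epithelium, and in controls. AT1 cells at P5 and AT2 cells at P8 to P9 had 3 control and 3 mutant libraries each, and whole lung at P14 had 1 of each. Summed FPKM was 458300 to 614500 in AT1 libraries, 536900 to 983400 in AT2 libraries, and 715800 and 625400 in control and mutant lung. Between 11102 and 12561 loci reached 1 FPKM in a cell-type library.

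Nkx2-1 (chromosome 12: 56531958 to 56536908, minus strand) was lower in every mutant library. In AT1 cells it measured 262, 281 and 239.8 FPKM in controls A to C and 22.8, 55.8 and 68.2 in mutants A to C, a log2 change of -2.53 ± 0.36 (SE; n = 3 per arm; limma adjusted p = 0.00639). In AT2 cells it measured 247, 289 and 353 FPKM in controls and 74.4, 59.0 and 73.4 in mutants (log2 -2.08 ± 0.16, adjusted p = 7.31e-05). Mutant libraries held 8.74, 21.4 and 26.1% of the control mean in AT1 cells and 25.1, 19.9 and 24.8% in AT2 cells. Whole lung held 101.1 FPKM in the control and 52.1 in the mutant. A gene-level value can include transcript from outside a deleted part.

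**Figure D1:**
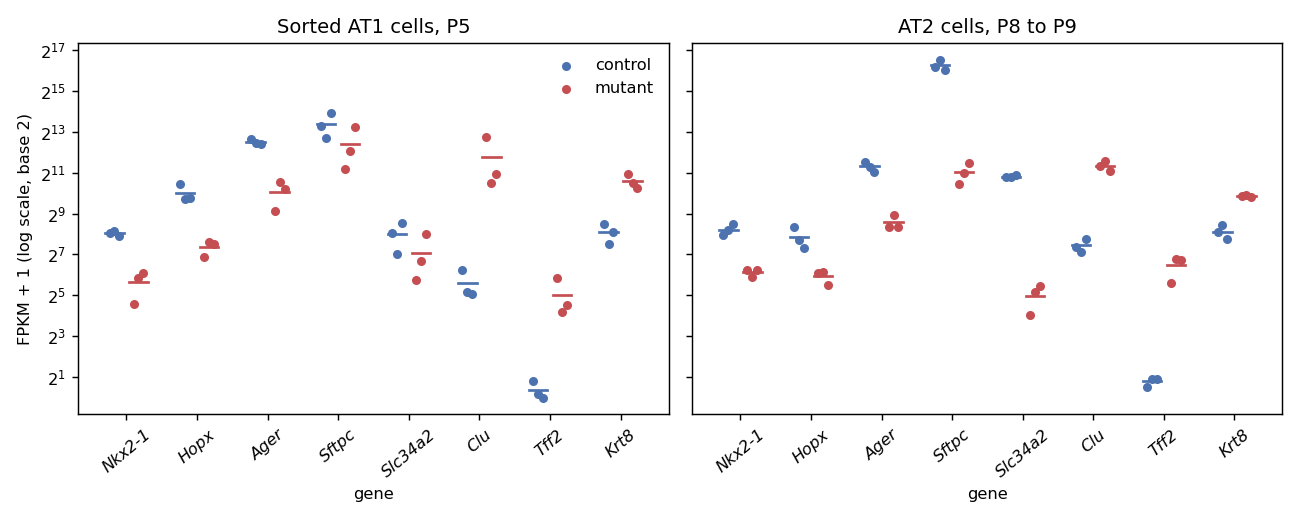
Levels of 8 genes in AT1 cells at P5 (left) and AT2 cells at P8 to P9 (right), as FPKM + 1 on a base-2 log axis, with 1 point per library (control blue, mutant red) and a line at the arithmetic mean of 3. Sftpc averaged 77609.4 FPKM in control AT2 cells and 2059 in mutants, while the ranges of its AT1 libraries overlapped.

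The AT1 comparison asked which genes depend on Nkx2-1 in these cells. Genes typical of AT1 cells fell: Hopx, a homeodomain cofactor, from 1041 ± 308 to 161 ± 41.2 FPKM (mean ± SD, n = 3; 6.45-fold), and Ager, the receptor for advanced glycation end products on the AT1 cell surface, from 5797 ± 491 to 1062 ± 475 (5.46-fold). Genes with little or no signal in controls appeared at high levels: Sprr1a, a cornified-envelope protein of squamous epithelium, rose from 1.39 ± 1.201 to 1206 ± 562 FPKM, and Cym, which encodes the stomach protease chymosin, from 2.59 ± 3.36 to 1413 ± 576. Clu, which encodes the secreted chaperone clusterin, rose from 47.0 ± 23.0 to 3448 ± 3052 FPKM, with mutant A at 6959.8 and mutants B and C at 1438 and 1948. These 5 genes passed the limma test, with adjusted p from 7.46e-05 (Sprr1a) to 0.00697 (Ager). All 28 measured cell cycle genes rose, with limma adjusted p up to 0.0433 (Bub1), and 15 of them passed where no filter on low values was used.

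Of 26 measured AT1 cell genes, 19 fell, none rose and 7 did not pass (20 fell when adjusted over the list alone). Sec14l3 fell 9.35-fold and Scnn1g, the gamma subunit of the epithelial sodium channel, 5.09-fold (adjusted p = 0.00463 and 0.0124). The list's median log2 change was -1.46 (camera adjusted p = 4.5e-13; adjusted p = 0.533 with an estimated correlation). Basement membrane genes went the same way, with 9 of 18 lower and none higher over all genes and adjusted over the list alone. With letters as a block 9 were lower and 1 higher. Col4a3, Col4a4 and Agrn are in this list and in that of AT1 cell genes, so these results are not independent. The collagen IV chains Col4a3 (chromosome 1: 82586921 to 82722059) and Col4a4, which form the network shared by lung and kidney, fell by 2.69 ± 0.40 and 2.53 ± 0.35 on the log2 scale. Col4a1 and Col4a2 fell by 1.29 ± 0.23 and 1.49 ± 0.26, calls that were lost without mutant A. The list gave adjusted p = 2.0e-05, and adjusted p = 0.533 with an estimated correlation. Outside the lists, Wnt3a, a secreted Wnt ligand, fell from 33.3 ± 9.70 to 3.92 ± 2.76 FPKM and Tmod1, an actin-capping tropomodulin, from 17.7 ± 6.51 to 1.78 ± 0.84.

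The gastric list rose in 5 of its 7 measured members, also when adjusted over the list alone, and none fell. With letters as a block 5 rose and 1 fell. The list holds 23 genes, and the filter on low values admits those silent in controls only where mutants express them. With no filter, an alternative chosen after seeing the data, 17 were tested and 3 rose, with a median of 0.67 in place of 2.96 (adjusted p = 4.59e-05). Cym (chromosome 3: 107211293 to 107221732) rose by 8.96 ± 0.62 and Tff2, a mucosal trefoil peptide, by 4.54 ± 0.42 on the log2 scale. Tff1 was listed at 0 in all 3 controls and measured 23.1, 3.06 and 3.78 FPKM in mutants A to C. The list had adjusted p = 0.00312 (adjusted p = 0.533 with an estimated correlation), and the call was lost without any one of the mutant libraries, where members silent in controls drop below the filter. Of 7 measured intestinal genes, from 27 listed, 1 rose, over all genes and over the list alone: Hnf4a, a transcription factor of gut and liver epithelium, from 0.0178 ± 0.0166 to 9.16 ± 8.06 FPKM. That list did not pass (adjusted p = 0.61), and its median changed sign with the rescaling of libraries.

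The alveolar transitional list, genes reported in cells between the AT2 and AT1 states, rose in 10 of 15 members, also over the list alone, with none lower (adjusted p = 7.6e-07; adjusted p = 0.431 with an estimated correlation). With letters as a block 10 rose and 1 fell. Sprr1a (chromosome 3: 92483952 to 92485895) led with a log2 change of 8.99 ± 0.40, followed by Clu at 5.91 ± 0.58. Among pan-epithelial genes 8 of 11 rose and none fell, while 1 fell when adjusted over the list alone (adjusted p = 0.000232; adjusted p = 0.533 with an estimated correlation). The simple-epithelium keratins Krt8 and Krt18 rose 5.69- and 4.75-fold (adjusted p = 0.0039 and 0.00463), and Krt19 rose 4.24-fold. Median change of the 28 cell cycle genes was 1.59 (camera adjusted p = 3.4e-13, and 0.533 with an estimated correlation), and all 28 also passed over the list alone. With no filter on low values 15 passed, while all 28 still lay above 0. Cdk1, the mitotic kinase, rose from 4.30 ± 2.53 to 20.4 ± 1.61 FPKM and the cyclin gene Ccnb1 from 4.14 ± 2.51 to 19.8 ± 1.86; both calls were lost without mutant A, at log2 changes of 2.10 and 2.22.

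Of 20 lung epithelial transcription factors, 5 rose, 3 fell and 12 did not pass (6 and 5 adjusted over the list alone; 6 and 6 with letters as a block). The ETS factors Ehf and Elf3 rose 9.11- and 5.78-fold and Id2, an inhibitor of helix-loop-helix factors, 2.37-fold. Hopx and Tead1 were among those that fell, Tead1 by 1.04 ± 0.30 on the log2 scale (adjusted p = 0.0497), a call lost without control A, control C, mutant A or mutant B. As a list they did not pass (adjusted p = 0.61), with a median of -0.25 and a mean of 0.01. YAP and TAZ targets, read-outs of Hippo signalling, included 2 lower genes of 12, Tead1 and Lats2, none over the list alone and 3 with letters as a block (adjusted p = 0.0249; adjusted p = 0.576 with an estimated correlation). The Lats2 call was lost without any one of the 6 libraries, and without mutant A the list had adjusted p = 0.115.

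AT2 cell genes were present in the AT1 sort at high levels in both arms. Sftpc, which encodes surfactant protein C, measured 10055, 6728 and 15305 FPKM in controls A to C and 2311, 4288 and 9584 in mutants A to C, a difference that did not pass (log2 -1.15 ± 0.55, adjusted p = 0.179). Of 24 AT2 genes 2 rose (Muc1 and Il33), 2 fell (Lyz1 and Chil1) and 20 did not pass, with the same counts over the list alone. With letters as a block 3 rose and 10 fell, Lpcat1 among them (adjusted p = 0.0197 in place of 0.156). The list median was -0.95 (camera adjusted p = 0.00582, or 0.61 with an estimated correlation, and fry adjusted p = 0.364). All 4 single-gene calls were lost without mutant A and where no filter on low values was used. Surfactant lipid synthesis genes did not pass (1 higher and 1 lower of 19; 0 and 1 over the list alone; adjusted p = 0.112).

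Markers of other cell types also moved. Endothelial genes had a median of -0.76, with 3 of 14 lower over all genes and 9 over the list alone. Their camera adjusted p was 0.000138, or 0.576 with an estimated correlation, and fry gave adjusted p = 0.183. Leukocyte genes had 1 of 14 lower (Csf1r; none over the list alone) and mesenchymal genes 1 of 13 (Tcf21, also over the list alone), with adjusted p = 0.00407 and 0.0152; both genes lost their call without mutant A or mutant C. Airway genes had none of 7 past the gene test (adjusted p = 0.0301), with Scgb3a2 at log2 -2.39 ± 0.83 (adjusted p = 0.0818, and 0.0479 with letters as a block). Interferon response genes had 1 of 8 lower, Ifit3 by 2.08 ± 0.16 on the log2 scale (adjusted p = 0.0467 for the list, and 0.0757 with no filter on low values). Each of these last 4 lists had adjusted p = 0.576 with an estimated correlation and lost its call without at least 1 library. Mesothelial genes (2 of 6 higher, Upk1b and Msln; adjusted p = 0.531), immediate early and heat shock genes (none of 12; adjusted p = 0.0567) and MHC class II genes (none of 6; adjusted p = 0.28) did not pass; counts over the list alone were the same. The Msln call was lost without control B, control C or any one mutant library, under all 4 rescalings and without the filter on low values. With letters as a block 5 endothelial, 5 leukocyte, 3 airway and 3 interferon genes were lower. The mesothelial median was -0.07 and the mean 0.53. Just 2 erythroid genes were measured.

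In total 1462 genes were higher and 785 lower in mutant AT1 cells, of 12612 tested with limma (965 of them changed at least 2-fold). With letters as a block these counts were 1907 and 1359. Rescaling libraries to equal totals gave 686 higher and 652 lower and moved the median of all genes by -0.12; rescaling without mitochondrial and small RNA loci, chosen after seeing the data, gave 1131 and 980. Mutant A carried much of the count: 473 genes passed without it, against 1066 without mutant B, 1119 without mutant C and 1345 without control C, and 20 named genes lost their call without mutant A.

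The AT2 comparison asked the same question in AT2 cells, where the genes of surfactant proteins fell. Sftpc fell from 77609.4 ± 13154 to 2059 ± 704 FPKM (37.7-fold), Sftpb from 8924 ± 948 to 327 ± 124 (27.3-fold) and Sftpa1 from 3659.8 ± 526 to 102 ± 35.0 (35.7-fold). Slc34a2, which encodes the phosphate transporter of the AT2 apical membrane, fell from 1794 ± 77.2 to 30.7 ± 13.8 FPKM (58.4-fold; chromosome 5: 53038081 to 53071664). Rising genes again included Cym, from 2.03 ± 0.91 to 186 ± 41.1 FPKM, Tff2, from 0.73 ± 0.25 to 87.5 ± 34.2, and Clu, from 172 ± 40.7 to 2604 ± 461. All adjusted p were between 7.22e-06 (Cym) and 0.000257 (Sftpc), n = 3 per arm; the Sftpc call was lost (adjusted p = 0.167) where no filter on low values was used.

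Of 21 measured AT2 cell genes, 20 fell and 1 (Muc1) did not pass, with the same counts over the list alone. The median log2 change was -3.55 (adjusted p = 1.8e-13; adjusted p = 0.276 with an estimated correlation). Lamp3, a lysosome-related membrane protein of lamellar bodies, fell 27.7-fold and Rbpjl, an RBPJ-like transcription factor, 71.5-fold. Surfactant lipid genes fell in 12 of 13 cases, also over the list alone, among them the lipid transporter Abca3 (7.36-fold) and the acyltransferase Lpcat1 (17.6-fold). That list had adjusted p = 4.8e-09, and adjusted p = 0.188 with an estimated correlation. MHC class II genes fell in all 6 cases over all genes and over the list alone (median -2.01; adjusted p = 0.000112; adjusted p = 0.403 with an estimated correlation), with H2-Aa down 7.07-fold. AT2 cells and leukocytes both express these genes, and leukocyte genes fell too (median -1.55), so the source of the drop stays open.

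AT1 cell genes were mixed in AT2 cells, with 12 of 25 lower, 3 higher and 10 not past, and the same counts over the list alone (adjusted p = 0.0042; adjusted p = 0.553 with an estimated correlation). Ager fell from 2521 ± 421 to 378 ± 92.3 FPKM and Hopx from 229 ± 84.9 to 60.3 ± 13.3. Ager averaged 5797 FPKM in control AT1 cells, so carried-over AT1 cells may hold such transcripts in the AT2 libraries. These falls need not be changes within AT2 cells, which was not tested. The list median of -0.59 became -0.01 when libraries were rescaled to equal totals. With fry the list had adjusted p = 0.0945. Gastric genes rose in 4 of 5 measured cases, from 23 listed, also over the list alone (adjusted p = 0.0344; adjusted p = 0.403 with an estimated correlation), and the filter again favours members that mutants express. With no filter 7 of 14 rose and the median was 0.31 in place of 3.04 (adjusted p = 0.000739). Their call was lost with letters as a block (adjusted p = 0.0507) and without control B or any mutant library. Of 7 measured intestinal genes, from 27 listed, 4 rose, over all genes and the list alone, Hnf4a by 3.78 ± 0.18 and the tetraspanin gene Tspan8 by 1.76 ± 0.17 on the log2 scale, though the list did not pass (adjusted p = 0.0801).

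All 24 measured cell cycle genes rose, also over the list alone (median 2.11; adjusted p = 5.0e-10; adjusted p = 0.403 with an estimated correlation). Top2a, a topoisomerase of dividing cells, rose 5.77-fold and the mitotic kinase gene Plk1 5.57-fold. Transitional genes rose in 12 of 14 cases with none lower, while 1 was lower over the list alone (adjusted p = 0.000195; adjusted p = 0.188 with an estimated correlation). Pan-epithelial genes had 8 of 10 higher and 1 lower, also over the list alone (adjusted p = 0.00568; adjusted p = 0.403 with an estimated correlation), with Krt19 up 5.56-fold and Krt8 up 3.37-fold. Itgb4, the hemidesmosome integrin chain, rose from 0.78 ± 0.21 to 29.9 ± 3.48 FPKM and Scara3, a scavenger receptor family member, from 1.14 ± 0.54 to 71.98 ± 4.31. Basement membrane genes split, with 8 of 17 higher and 5 lower over all genes and the list alone (adjusted p = 0.474). The laminin chain gene Lamc1 rose 2.98-fold while Col4a3 fell 3.17-fold. Of 16 transcription factors 4 rose and 6 fell, also over the list alone (adjusted p = 0.179); Etv5, Elf5 and Cebpa fell, with log2 changes of -3.55 ± 0.10, -2.88 ± 0.16 and -2.55 ± 0.20, and Ehf, Elf3, Klf5 and Tead4 were the risers, the Elf3 call being lost under 7 other settings. YAP and TAZ targets had 3 of 11 higher (Ajuba, Ptpn14 and Crim1), also over the list alone (adjusted p = 0.345).

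Markers of several other cell types were lower in the mutant AT2 libraries. All 14 endothelial genes fell, also over the list alone (median -1.30; adjusted p = 1.1e-05), Cldn5 from 36.3 ± 6.45 to 11.8 ± 5.01 FPKM. Of 8 leukocyte genes 7 fell (8 over the list alone; adjusted p = 0.00274), and of 8 mesenchymal genes 6 fell and 1 rose (7 and 1 over the list alone; adjusted p = 0.00842). Immediate early and heat shock genes, which respond to cell handling, fell in 6 of 10 cases (7 over the list alone; adjusted p = 0.00274), with Dusp1 down 5.43-fold. These 4 lists all had adjusted p = 0.403 with an estimated correlation. With fry the immediate early and heat shock list had adjusted p = 0.0555. Interferon genes had 3 of 6 lower (adjusted p = 0.0851; 0.0436 with no filter) and erythroid genes none of 4 (adjusted p = 0.454), the same over the list alone, and both medians changed sign with rescaling, as did that of the transcription factors. Few airway (2) and mesothelial (1) genes were measured: Upk3b, the mesothelial one, rose from 0.246 ± 0.186 to 2.65 ± 0.801 FPKM (adjusted p = 0.000779), while among airway genes Cyp2f2 fell (log2 -0.88, lost with equal totals) and Bpifb1 did not pass (adjusted p = 0.0815). Mitochondrially encoded transcripts took 12.8, 11.5 and 8.85% of FPKM in mutants A to C against 33.7, 27.7 and 14.0% in controls A to C.

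**Figure D2:**
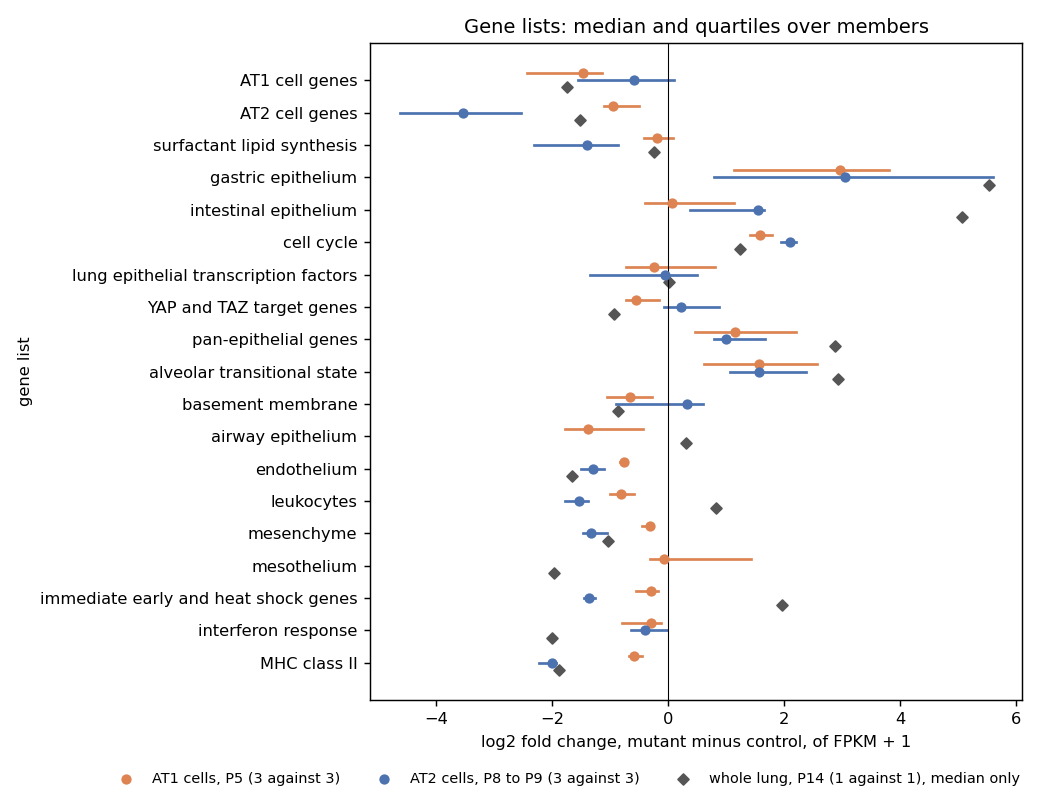
Median (points) and quartiles (bars) of the log2 change of list members, mutant minus control, on log2(FPKM + 1), for AT1 cells at P5, AT2 cells at P8 to P9 and, as medians, whole lung at P14. AT2 cell genes had medians of -0.95, -3.55 and -1.51, and cell cycle genes lay above 0 in all 3. The erythroid list is not drawn, and lists with fewer than 3 measured members have no point. Signs changed with rescaling for the intestinal list in AT1 cells, the interferon list in AT2 cells and the transcription factors in AT2 cells and lung.

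Of 11610 genes tested in AT2 cells with limma, 3767 were higher and 2589 lower; 1881 of these changed at least 2-fold (914 higher and 967 lower). Rescaling moved the balance of directions. Equal totals gave 6368 higher and 996 lower with the median of all genes at 0.6 in place of 0.09, and totals without mitochondrial and small RNA loci, chosen after seeing the data, gave 5381 and 1518 with the median at 0.35. Changes on the scale of 1.5-fold therefore depend on the scaling, and those of the surfactant, gastric and cell cycle genes kept their direction.

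The fit over both cell types asked which mutant effects differed between AT1 and AT2 cells, at the ages sampled. AT2 genes were lowered more in the AT2 libraries. Slc34a2 changed by -5.93 there and by -1.07 in the AT1 libraries on the log2 scale, a difference of -4.86 ± 0.76 (limma adjusted p = 0.00358). Rbpjl differed by -4.22 ± 0.67 (adjusted p = 0.00396). Control means in AT2 cells and in the AT1 sort were 1794 and 255 FPKM for Slc34a2, and 109 and 13.8 for Rbpjl. Carried-over AT2 cells may hold these transcripts in the AT1 sort, and each cell type had its own cross. These differences between libraries therefore need not be differences of effect between AT1 and AT2 cells. Bex1, an X-linked gene (136213972 to 136215513) encoding a small adaptor protein, fell in AT2 cells from 559 ± 96.9 to 173 ± 31.7 FPKM but rose in AT1 cells from 7.90 ± 3.24 to 55.2 ± 13.1 (difference -4.38 ± 0.35, adjusted p = 7.99e-05). Chil4, a chitinase-like protein gene, rose in AT2 cells from 1.53 ± 0.78 to 42.9 ± 29.6 FPKM and stayed below 0.1 FPKM on average in both AT1 arms (difference 3.91 ± 0.59, adjusted p = 0.00313). Fras1, a basement membrane gene, differed by 2.35 ± 0.36 (adjusted p = 0.00348).

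Of 10336 genes tested for a difference, 415 had a more positive and 442 a more negative effect in AT2 cells (limma; 476 at least 2-fold). With letters as a block these were 673 and 672. Equal totals gave 3025 and 233, and totals without mitochondrial and small RNA loci 2760 and 303, so the balance of directions depends on the scaling. Totals fell to 541, 407, 420, 532 and 436 without AT2 control A, AT2 control B and AT2 mutants A, B and C. By list, AT2 cell genes (median -2.75; 15 of 21 more negative, 17 over the list alone; adjusted p = 1.9e-15) and surfactant lipid genes (-1.12; 7 of 14, 11 over the list alone; adjusted p = 1.7e-10) had more negative effects in AT2 cells. With an estimated correlation both had adjusted p = 0.263. The limit given above for Slc34a2 and Rbpjl holds for the AT2 cell genes as a list. Basement membrane genes (1.13; 9 of 17 more positive, 11 over the list alone; adjusted p = 2.9e-06) and YAP and TAZ targets (0.87; 3 of 11, 5 over the list alone; adjusted p = 0.000905) had more positive effects, and both had adjusted p = 0.451 with an estimated correlation. AT1 cell genes were lowered more in the AT1 libraries (median difference 1.06, with 2 of 25 more positive and 6 over the list alone). Their camera adjusted p was 0.000427, or 0.604 with an estimated correlation, and fry gave adjusted p = 0.26. Carried-over AT1 cells may hold these transcripts in the AT2 libraries, so this need not be a difference of effect between AT1 and AT2 cells. Nkx2-1 itself did not differ (0.45, adjusted p = 0.554). No difference passed for gastric (adjusted p = 0.0594; 0.00792 with no filter), cell cycle (0.0572; 0.0467 with letters as a block and 0.0276 with no filter), intestinal (0.23), transcription factor (0.165), pan-epithelial (0.488), transitional (0.245), airway (0.245), leukocyte (0.13), mesenchymal (0.13), mesothelial (0.952) or interferon genes (0.424). Erythroid genes were too few to test. Medians of the pan-epithelial (-0.21 to 0.34), transcription factor, interferon and erythroid differences changed sign when libraries were rescaled to equal totals.

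Calls overlapped between the cell types. Among 9147 genes tested in both, 907 were higher in both, where independent lists would share 379.6 (Fisher's exact p = 1.07e-265), and 399 were lower in both against 123 (p = 4.44e-145). Opposite calls numbered 36 against 434. The log2 changes correlated across genes at Pearson's r = 0.69 and Spearman's rho = 0.66; genes are not independent replicates. The 1306 calls in a shared direction dropped to 466 at a 2-fold minimum and to 322, 668, 688 and 830 without AT1 mutants A, B, C and control C.

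**Figure D3:**
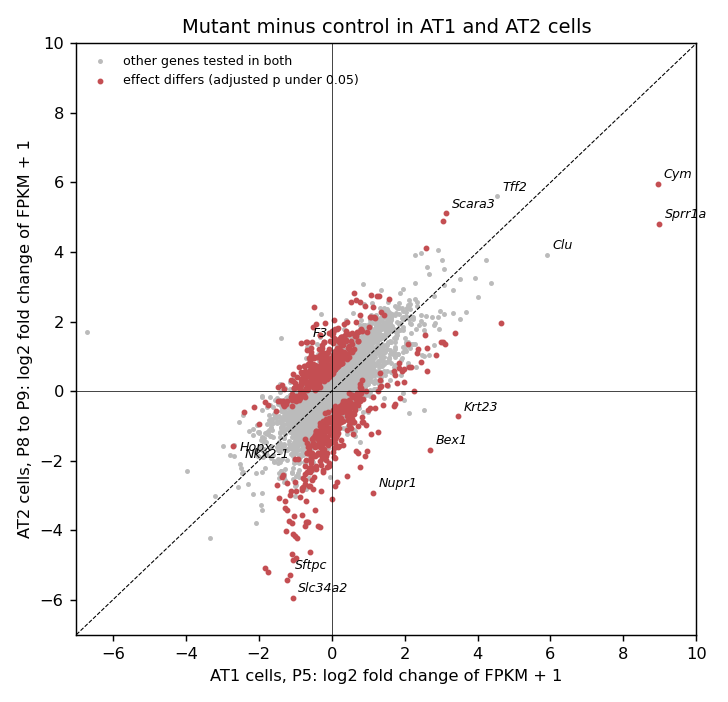
Log2 change of FPKM + 1, mutant minus control, in AT1 cells at P5 (x axis) against AT2 cells at P8 to P9 (y axis), 1 point for each of 9147 genes; red points are 753 genes whose effects differed (limma interaction, adjusted p under 0.05) and the dashed line marks equal effects. Sprr1a, Cym and Tff2 lie far above 0 on both axes, while Bex1, Nupr1 and Krt23 lie right of 0 and below it.

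Whole lung at P14 extended the comparison to the later organ, with 1 library per group and hence no replicate check. Gastric genes reached high levels in the mutant lung: Tff1 measured 0.125 FPKM in the control and 817 in the mutant, and Tff2 10.9 and 1373. Intestinal genes did so too, with Spink4, a goblet cell peptide gene, at 2.62 and 1022 FPKM and Apoa1, an apolipoprotein gene, at 0.14 and 146. Clu measured 65.6 and 7803 FPKM, and Sprr1a 0.492 and 414. Sftpc measured 20482 FPKM in the control and 6174 in the mutant.

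All 13 measured gastric genes were at least 2-fold higher (median log2 ratio 5.54, above 100% of matched random lists), as were 12 of 13 intestinal genes (5.06, 100%), 10 of 10 pan-epithelial genes (2.87, 100%), 11 of 15 transitional genes (2.93, 100%) and 16 of 25 cell cycle genes (1.25, 100%). The minimum of 5 FPKM admits genes silent in control lung only where the mutant expresses them, so just 13 of 23 gastric and 13 of 27 intestinal genes were measured. With a minimum of 1 FPKM these medians were 3.44 and 4.72, and with a pseudocount of 0.1 they were 7.18 and 7.44. AT1 cell genes were at least 2-fold lower in 20 of 26 cases (-1.75, percentile 0) and AT2 cell genes in 14 of 24 (-1.51, percentile 0), while Muc1 was 7.87-fold higher. Surfactant lipid genes (-0.24, percentile 2.63), YAP and TAZ targets (-0.93, percentile 0.09) and basement membrane genes (-0.86, percentile 0) lay low. Transcription factors lay at 0.01 (percentile 26.1), a sign that rescaling turned, with Elf3 at 8.14 and 367 FPKM. Markers of other cells moved as well: endothelium (-1.66, percentile 0), mesenchyme (-1.03, percentile 0.01), mesothelium (-1.96, percentile 0.01; 3 of 4 genes lower), interferon response (-1.997, percentile 0.02) and MHC class II (-1.88, percentile 0) lay low. The fourth mesothelial gene, Msln, was 8.91-fold higher. Leukocytes (0.82, percentile 99.7) and immediate early and heat shock genes (1.96, 100%) lay higher, and airway epithelium (0.31, percentile 68.3) lay within what random lists gave. Both erythroid genes measured, Hbb-bt and Alas2, were lower, at 4.21- and 3.50-fold.

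Of 10532 genes at 5 FPKM or more, 1366 were at least 2-fold higher and 1185 lower in the mutant lung. The 10 largest decreases were all small RNA loci listed at 0 in the mutant. Among genes called higher in AT1 cells, 1119 of 1213 (92.3%) were also higher in the P14 mutant lung, against 54.9% of all measured genes, and among those called lower 547 of 688 (79.5%) were lower, against 45.1%. For AT2 calls the shares were 68.4% and 62.7%.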

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

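The counts over other splits of the libraries and the shares of Sftpc by letter were chosen after the values had been seen, while the correlation and ratio computed for AT2 cell genes in the AT1 sort were set before their values were seen.

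The mutant effect differed between AT1 and AT2 cells, by the interaction test, for 857 genes. Of 100 splits of genotype labels within each cell type, 3 gave as many, the real one included, and the highest other count was 2745. Splits that mix the AT2 arms lose the AT2 effect and gave at most 82 genes, and of the 7 that kept the AT2 arms whole 3 gave as many, the real one included. Among those 7, the counts of 2450 and 2745 came from splits that put AT1 control A and mutant A on one side. A split with the same AT1 sides as the one with 2745, but with the AT2 arms swapped, gave 580. That placement of letter A therefore does not by itself give the high counts. Splits that part all 3 lettered AT1 pairs, as the real one does, gave 302 and 342. Such splits are too few for a share under 0.05, so their count does not settle whether chance can be excluded. The high counts point to a structure of the samples, the AT2 genotype itself. For the AT1 and AT2 gene counts, 10 splits each were too few for a share under 0.05; the real counts were 2247 and 6356 and the highest others 2 and 5, with 1 split as large as the real one, itself, in each. Among the 4 AT1 splits that part all 3 lettered pairs, the highest other count was 1; the others keep both libraries of 1 letter on one side.

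Named genes stood out for the same reason, an effect that differed between the cell types by the interaction test, given as the AT2 change minus the AT1 change on the log2 scale. The differences above 0 were Chil4 3.91, Cp 2.91, Fras1 2.35, Abi3bp 2.34, Sphk1 2.23, F3 2.07, Scara3 1.98, Fxyd6 1.85, Ajuba 1.70, Tspan8 1.69, Ptpn14 1.59, Itgb4 1.53, Upk3b 1.47, Lamc1 1.28 and Plaur 1.09. Those of surfactant and other AT2 genes lay below 0, at Slc34a2 -4.86, Rbpjl -4.22, Sftpc -4.13, Lamp3 -3.83, Sftpb -3.77, Sftpa1 -3.46, Lgi3 -3.26, Lpcat1 -3.04, Etv5 -2.75, Muc1 -2.08, Abca3 -2.02, Insig1 -2.01, Elf5 -1.91 and Cebpa -1.82. Other differences below 0 were Bex1 -4.38, Krt23 -4.20, Sprr1a -4.18, Nupr1 -4.05, Cym -3.002, Gsta4 -2.69, Id2 -2.44, Upk1b -2.08, Tnip3 -1.39 and Col3a1 -1.11. The Cp call was lost without most single libraries.

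Lists differing by the same test had median differences of 1.06 for AT1 cell genes, -2.75 for AT2 cell genes, -1.12 for surfactant lipid synthesis, 0.87 for YAP and TAZ targets, 1.13 for basement membrane, -0.60 for endothelium, -1.09 for immediate early and heat shock genes and -1.51 for MHC class II. The last 3 had adjusted p = 0.0161, 0.00234 and 0.0125, and adjusted p = 0.623, 0.604 and 0.604 with an estimated correlation. With fry they had adjusted p = 0.401, 0.274 and 0.274. With equal totals their medians shrank to -0.10, -0.54 and -0.99, though no median of the lists named here changed sign. The endothelial call was lost without AT1 control A, AT1 control C, AT2 control C or AT2 mutant A.

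AT2 cell genes in the AT1 sort made a pattern of their own: of 21 measured in both cell types, 18 had a log2 change below 0 in the AT1 mutants and 3 above, though just 2 passed as lower and 1 as higher. Sftpc in mutants A to C was at 23.0, 63.7 and 62.6% of the control of the same letter (21.6, 40.1 and 89.6% of the control mean). If fewer carried-over AT2 cells with their normal programme were the source, the genes would fall alike, and across the 21 genes the AT1 and AT2 changes would correlate weakly; Spearman's rho was 0.60 (permutation p = 0.00478; bootstrap interval 0.188 to 0.849), an interval too wide to exclude it. If the carrying cells had lost Nkx2-1, changes should follow those of AT2 cells at a ratio of at least 0.25, and the median ratio was 0.23, just short of it. Both explanations stay open and cannot be told apart here, and a mix of the 2 may apply.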

How the results depend on the processing

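The rescaling to equal totals without mitochondrial and small RNA loci and the list tests with no filter on low values were chosen after seeing the data; the other settings were planned. Count tools for raw reads were planned for count tables and not run, since the values are FPKM.

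Where a count moved by over 1.5 times the cause was not tested, except that a 2-fold minimum passes fewer genes by construction. Leaving out a library need not lower a count: differing effects rose from 857 to 1038 without AT1 control A. AT1 calls went from 2247 to 965 at a 2-fold minimum and 1338 with equal totals, AT2 calls from 6356 to 1881 at a 2-fold minimum, and shared calls from 1306 to 466. Differing effects went from 857 to 476 at a 2-fold minimum, 3258 with equal totals, 3063 with equal totals without mitochondrial and small RNA loci and 1473 with array quality weights. Leaving out single libraries gave 473 to 1990 AT1 calls, 4944 to 6052 AT2 calls, 407 to 1038 differing effects and 322 to 1353 shared calls; where 2 libraries were left in an arm, limma still pooled the spread over both arms. Nkx2-1 ranged from -2.83 to -2.06 in AT1 cells and from -2.21 to -1.95 in AT2 cells.

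Letters as a replicate block gave 3266 AT1 calls, 6249 AT2 calls and 1345 differing effects. Block fits ended the AT1 call of Elovl6 (adjusted p = 0.0558) and the AT2 gastric list, and added Scgb3a2 and the cell cycle list of the interaction (adjusted p = 0.0467). They changed no other call of a list, or of a gene in the comparison it was named for. Further list members gained AT1 calls, AT2 cell genes going from 2 higher and 2 lower to 3 and 10. Some went against their list, with 1 gastric and 1 transitional gene lower and 1 basement membrane gene higher.

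List calls numbered 13 of 19 in AT1 cells, 12 of 18 in AT2 cells and 8 of 19 for the difference. With an estimated correlation 0, 0 and 0 passed (lowest adjusted p = 0.431, 0.188 and 0.263), and with fry 6, 14 and 4. In AT1 cells fry lost AT2 cell, YAP and TAZ, airway, endothelial, leukocyte, mesenchymal and interferon genes (adjusted p from 0.145 to 0.364). In AT2 cells it lost AT1 cell and immediate early genes and gained intestinal, transcription factor, YAP and TAZ, and interferon genes. For the difference it lost AT1 cell, endothelial, immediate early and MHC class II genes. With no filter on low values 12, 13 and 10 passed; the AT1 interferon call was lost, and AT2 interferon genes and the differences of gastric and cell cycle genes gained one. Leaving out single libraries left 10 to 13, 11 to 12 and 7 to 10. In whole lung the transcription factor median turned from 0.01 to -0.036 on rescaling by the median ratio, and no other lung list reversed, while 15 of 57 lung list values moved. In the cell types the medians of AT1 intestinal genes, of AT2 transcription factor, interferon and erythroid genes, and of 4 lists of the difference changed sign with a rescaling.

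Among 67 named genes in AT1 cells, 1020 of 1111 values under other settings kept direction and side of the threshold, 89 lost the call and 2 gained it. For 77 in AT2 cells, 1348 of 1363 kept it and 15 lost it, and for 8 named for the difference 165 of 176 kept it. List results kept it in 171 of 209 values in AT1 cells, 174 of 198 in AT2 cells and 293 of 323 for the difference. Without mutant A 20 of 62 AT1 genes lost their call, among them Rgcc, Cldn4 and Ube2c, against 7 and 10 without mutants B and C, and 7, 6 and 10 of 67 without controls A, B and C. Equal totals moved the median of all genes by -0.12 in AT1 cells, and to 0.60 in AT2 cells and 0.53 for the difference. Of 18317 AT1 loci above 0, 12612 were tested, and without the filter 1580 passed.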

Other observations

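The mutant A tests, the scale factor test of mitochondrial transcripts and the genes of the next 2 paragraphs were chosen after their values were seen; the test of nuclear oxidative phosphorylation genes was set before.

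Some genes moved in opposite directions. Nupr1, a stress-response chromatin protein gene, rose in AT1 cells from 45.8 ± 4.96 to 102 ± 18.6 FPKM (n = 3) and fell in AT2 cells from 282 ± 74.3 to 35.5 ± 1.64. Id2 rose 2.37-fold in AT1 cells and fell 2.33-fold in AT2 cells. F3, which encodes tissue factor, did the reverse, falling from 163 ± 7.87 to 103 ± 5.32 in AT1 cells and rising from 17.8 ± 6.08 to 47.6 ± 6.50 in AT2 cells. The interaction had limma adjusted p = 2.94e-05, 0.00259 and 0.00147 for the 3 genes. The F3 call in AT1 cells was lost without mutant A or mutant C.

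Other genes moved together in both. Carried-over AT1 cells may hold some of these transcripts in the AT2 libraries, which was not tested. Scnn1b, a second subunit gene of the epithelial sodium channel, fell 5.30-fold in AT1 cells and 7.33-fold in AT2 cells, and Shh, the hedgehog ligand gene, 4.63- and 7.41-fold. The Iroquois factors Irx1 and Irx2 fell 3.81- and 3.11-fold in AT1 cells and 5.25- and 3.67-fold in AT2 cells (adjusted p from 3.83e-05 to 0.018 over these 4 genes in both). Gpx2, a glutathione peroxidase gene, rose from 0.87 ± 0.23 to 34.8 ± 8.58 FPKM in AT1 cells and from 7.34 ± 0.73 to 112 ± 11.98 in AT2 cells, and Gsta4, a glutathione transferase gene, 23.3- and 3.91-fold. Aqp5, the aquaporin gene that names the cross of the AT1 libraries, fell from 450.3 ± 17.5 to 163 ± 44.0 in AT1 cells (limma adjusted p = 0.00583). Its change in AT2 cells did not pass (log2 -0.27, adjusted p = 0.406). The difference between the cell types did not pass either (1.23, limma interaction adjusted p = 0.0516). Whether the cross itself alters Aqp5 was not tested.

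AT1 mutant A changed more than mutants B and C and held the least Nkx2-1, 8.74% of the control mean. Over the 473 genes called without it, its log2 change was a median 1.29 times the mean of mutants B and C (interval 1.26 to 1.31; 84.8% of genes above 1). Measured against the control of its own letter, the median was 1.37 (interval 1.32 to 1.43; 81.8% above 1). Both are in line with a further-reaching mutant effect in that library, but the intervals run over genes of 1 library and leave out variation between libraries. Noise of that library stays open: over genes with little change, the SD of its deviations was 1.23 times that of mutants B and C (0.367 against 0.302 and 0.296), between the bounds set, and 1.34 times against same-letter controls. A larger recombined share of cells in that sort may explain it, which no label records.

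Mitochondrially encoded genes fell together in mutant AT2 libraries, by a median of 1.76 on the log2 scale, with 6 of 10 past the test. A scale factor would move every gene of a library alike, and the median of all tested genes was 0.0932. That median alone cannot decide this, since the deposited values already lay near a median-ratio scaling (-0.0066 after it). With equal totals the medians were -1.17 for mitochondrially encoded genes and 0.60 for all genes, the latter beyond the bound set. Under each of these scalings the mitochondrial genes fell against the other genes, which a scale factor alone does not give. The size of their fall depends on the scaling. Quantile normalization left the mitochondrial median at -0.29 with 4 of 10 past. Nuclear oxidative phosphorylation genes had a median of 0.14 over 27 genes (8 higher, 1 lower), and of 0.72 with equal totals (22 higher, 0 lower). A lower content of that machinery was predicted to lower these transcripts too, and they did not fall. The content of the machinery and of mitochondria was not measured, so transcripts alone do not decide it. Control C, at 14.0%, lay near the mutants. It was the P9 control, and the P9 mutant, mutant C, also had the lowest share of its arm, 8.85%. With 1 P9 library per arm, age and library cannot be told apart. No mitochondrial result is given here with postnatal day as a term. Leaving out single libraries gave medians of -2.27 to -1.40 with 2 to 10 genes past. RNA quality or handling differences were not tested.

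In the authors' deposited table, the AT1 fold-change column matched the values of its own row, within 0.0005, for 24 of 18317 loci, while the sorted columns matched in 100% of cases; Hopx is listed there at 0.73 and its own row gives -2.68. The AT2 column matched for 23608 of 23608 loci within its rounding. Deposited p-values equalled those of a test on log2(FPKM + 1) paired by letter for 18302 of 18317 AT1 loci and 23608 of 23609 AT2 loci, to within 1e-05.

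Sex-linked transcripts differed between libraries of one arm. Among AT1 libraries mutant B had Xist at 0.0623 FPKM and Ddx3y at 13.9, while the other 5 had Xist between 19.8 and 64.95. Among AT2 libraries Ddx3y measured 20.7 and 18.9 in controls A and C and 12.8 in mutant C. In whole lung Xist measured 52.6 in the control and 0.0848 in the mutant, so sex and genotype coincide there.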
